A study of Homo sapiens with 6 samples.

How the data were processed

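Small RNA was sequenced from 6 libraries of Panc3.27 cells, 3 of PLKO controls and 3 of shLIN28B, and samples were grouped and numbered by their titles. Per the labels' protocols, cells were infected with lentivirus in 10 µg/ml polybrene and selected from 24 hours later in 2.5 µg/ml puromycin for a minimum of 2 days, and the pooled populations were sequenced with 50 cycles per end on an Illumina HiSeq, in 2 pools of 6 libraries over 2 lanes. The labels name both a TruSeq RNA kit and a NEBNext small RNA kit with 15 amplification cycles, and do not say which library was in which pool. The deposited values are CPM, made by the authors from the reads counted over the listed pairs of a hairpin and a mature miRNA, and every column has the sum that CPM requires. The submitters' processing notes name edgeR 3.12 and hg19 with no role. The aligner, the counting rule and the miRNA annotation are not given in the sources used here.

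The 496 rows held 445 mature names on 356 hairpins, and 107 rows carried a star. In all, 92 rows belonged to 41 mature names listed on more than 1 hairpin, and 54 of these had values identical to another row of their name. These rows took 3.32% to 32.3% of a library's CPM, which would follow if reads that fit several hairpins were counted at each. In each library 100% of values were whole multiples of 1 read, within 0.001 reads. The recovered totals were 0.123% to 3.41% of the number of read pairs per sample that the labels state. PLKO control 3 held 94 low positive values where 100 were needed to check that its reads were recovered, so edgeR was run without that library. The thinning checks and the checks of zeros in that library took the smallest step of its values as 1 read. Among the shLIN28B libraries chi-square per degree of freedom was 5.35 to 8.05, so no pair agreed within sampling noise, and no libraries of either group were merged. Deposited group means were not used.

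The main test, its samples, the lists and the rule for named miRNAs were fixed before the data were examined. It was limma 3.58.1 with an intensity trend (R 4.3.3) on log2(CPM + 1), over miRNAs with a mean of at least 1 CPM in the 6 libraries, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no block. A fold change on this scale shrinks the ratio of low values. Where a library lists 0 it depends on the pseudocount and can exceed the ratio of the group means. Named were the let-7 family, up to 10 miRNAs per direction past the threshold (or, with fewer than 5, the 5 with the smallest p at a mean of at least 10 CPM), the 5 most abundant in controls and the members of each list with the smallest p. The 18 miRNAs that passed without PLKO control 1, miR-205 and the rows that PLKO control 3 listed at 0 were named after their values were seen. Lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, for lists with at least 3 tested members. Strand ratios were tested with limma on the log2 ratio, with 1 CPM added to each strand. Summed let-7 CPM was tested with an exact permutation test. The hairpin's target sequence was matched to GENCODE 29 transcripts of GRCh38. No other coordinates were taken from that build, since the submitters name hg19.

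Same-numbered libraries of the groups deviated together, with correlations of 0.35, 0.29 and 0.36 across miRNAs, each library correlating best with its own number. By the rule set for this comparison (every pair above 0.1) the numbers were taken to pair the samples, although the labels do not say that a number marks a shared culture or day. With 3 libraries per group the correlations of unlike numbers (-0.31 to 0.02) are not independent of these, so the rule cannot establish pairing. The blocked value is printed where it ends a call.

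Alternatives were other pseudocounts (0.1 and 5 CPM), filters, scalings, no trend, the replicate block and leaving out each library. Added after the data were seen were library weights, averaging rows of a mature name, settings combined with leaving out PLKO control 1 or PLKO controls 1 and 3, edgeR 4.0.16 quasi-likelihood tests on recovered reads without PLKO control 3, and a sign-flip test of summed let-7 over same-numbered pairs. Settings without PLKO controls 1 and 3 have 1 control library. Scripts ran in Python 3.11 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

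The fits were tested on simulated data with 200 changed miRNAs and known answers. With 6 libraries none of which stood apart, limma recovered 12.0%, 52.7% and 56.9% of changes of 2-fold, 4-fold and 8-fold, and 5.56% of its calls were false. Without PLKO control 1 the shares were 8.00%, 43.6% and 51.8%, with 7.81% false, and with PLKO control 1 given its own profile 0% at each fold. In the libraries none of which stood apart, edgeR without PLKO control 3 recovered 13.0%, 65.5% and 63.6%, with 7.23% false. edgeR was not tried on simulated libraries in which PLKO control 1 kept its own profile, so these shares do not cover that case. The simulation was changed after its first output was seen. At first the changed miRNAs could be of any abundance, and 46.8% of limma's calls were then false, because large changes in abundant miRNAs shift the CPM of all others. The changed miRNAs were then held under a mean of 500 CPM, and the shares above are from that version, so they do not cover changes in abundant miRNAs. Apart from the changes and the profile given to PLKO control 1, simulated libraries shared a mean profile, with an assumed dispersion of 0.05. The zeros particular to PLKO control 3 were not simulated, so the false shares do not cover calls that rest on them. The strand-ratio simulation was likewise tried with smaller changes first, of which few or none were recovered. The number of thinning draws in the checks of library differences was raised to 200 after runs with 20 draws gave unlike values, and the rule that such a check is void where the difference is absent before thinning was added after its first output. Thinning without PLKO control 3 was added later, and the check of a minimum read count in that library was rewritten 2 times after its value was seen, from values of 1 or 2 reads to the smallest CPM listed, because its read recovery was not verified. The tests of a label swap and of library scaling were rewritten after their first values were seen.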

Results

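Small RNA libraries from Panc3.27 cells, a human cell line established from pancreatic ductal adenocarcinoma, were compared to ask which microRNAs (miRNAs) change when LIN28B is knocked down with a short hairpin RNA. LIN28B is an RNA-binding protein that blocks the maturation of let-7 miRNA precursors. The series held 3 libraries of cells carrying the PLKO control plasmid and 3 libraries of cells carrying the LIN28B hairpin (shLIN28B). Only 1 hairpin was used, and LIN28B mRNA was not measured in these libraries, so the extent of the knockdown could not be checked here. The hairpin's target sequence, GCCTTGAGTCAATACGGGTAA, matched the LIN28B coding sequence on chromosome 6, positions 105026377 to 105026397 of the plus strand of GRCh38, in each of 3 annotated protein-coding transcripts. Abundance was given as CPM, the share of a library's counted reads scaled to a common total, for 496 pairs of a hairpin and a mature miRNA. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

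miR-21, a miRNA raised in many carcinomas, had the highest mean CPM over the 3 PLKO controls, followed by miR-27b, miR-203, miR-151-3p and miR-9. This order was not that of each control, since in PLKO control 2 miR-27b (108863 CPM) stood above miR-21 (101914 CPM). The library PLKO control 1 had a different profile from the other 5. miR-21 took 85.1% of its CPM against 10.2% to 16.2% in the others. miR-27b stood at 571 CPM in PLKO control 1 and 106069 in PLKO control 3, and miR-203, a miRNA of stratified epithelia, at 507 against 99130 and 96295. In the other direction, miR-205 stood at 22309 CPM in PLKO control 1 and at 1003 to 1536 in the others. Spearman's rho across miRNAs, which are not independent replicates, was 0.673 to 0.716 between PLKO control 1 and each other library and 0.854 to 0.940 among the other 5.

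**Figure D1:**
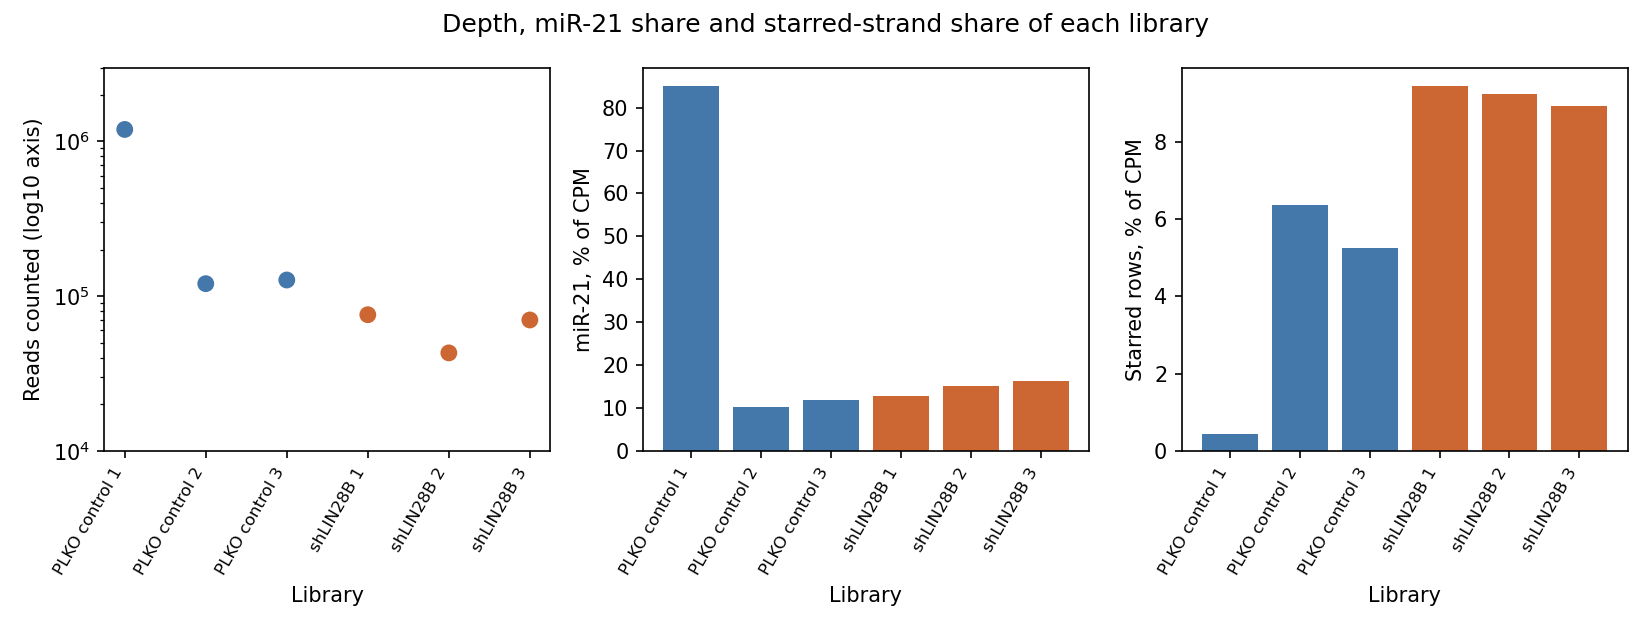
Reads counted (log10 axis), the percent of CPM taken by miR-21 and the percent taken by starred strands, for each of the 3 PLKO control libraries (blue) and 3 shLIN28B libraries (orange), 1 point or bar per library. PLKO control 1 had 1193602 reads and 85.1% miR-21, and starred strands took 0.425% of its CPM, 6.35% and 5.26% in the other controls and 8.93% to 9.44% in shLIN28B.

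The deposited values were whole multiples of 1 read, which gave 1193602 counted reads in PLKO control 1, 120307 in PLKO control 2, 127068 in PLKO control 3, and 75795, 42956 and 70105 in shLIN28B 1, 2 and 3. A count of 3 reads, the limit that a listed 0 allows, corresponded to 2.51 CPM in PLKO control 1 and 69.8 CPM in shLIN28B 2, the shallowest library. These limits cover counting error only, since reads amplified without molecular identifiers are not independent molecules. PLKO control 3 listed 264 pairs at 0 and PLKO control 2 148, at similar depth. PLKO control 1 listed no pair at 0, since each of the 496 pairs had a read there. The list therefore holds no miRNA that lacked reads in PLKO control 1, whatever its level in the other libraries. How the listed pairs were chosen is not given, and such miRNAs could not be tested.

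With all 6 libraries, no miRNA passed the test between shLIN28B and PLKO controls. Of the 496 pairs, 87 had a mean under 1 CPM and were left out. Of the others, tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, while 26 were higher and 0 lower at an unadjusted p under 0.05. The smallest adjusted p was 0.364, for miR-1301 (log2 fold change 5.87 ± 1.35, SE) and miR-577 (5.59 ± 1.32). miR-548o, miR-182* and miR-215 followed, at 6.21, 5.14 and 4.68 and an adjusted p of 0.412 each. These missed the threshold, as did the miRNAs with the smallest p among those lower in shLIN28B, which were miR-210, a hypoxia-responsive miRNA (-2.79 ± 2.04), miR-34c-5p, a target of p53 (-2.44 ± 2.01), miR-132 (-2.07 ± 1.87), miR-191 (-1.05 ± 0.90) and miR-423-5p (-1.07 ± 0.95). Without PLKO control 1 miR-210 moved to -1.27, miR-34c-5p to -0.79, miR-191 to -0.30 and miR-423-5p to -0.20. miR-132 was listed above 0 in PLKO control 1 only. The median log2 fold change of all tested miRNAs was 1.02, and 0.0050 once each library was centred on its median, so single fold changes are to be read against that shift. In simulated libraries in which PLKO control 1 kept its own profile, limma recovered 0% of changes of 2-fold, 4-fold and 8-fold, so the count of 0 does not show that miRNAs were alike.

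Leaving out PLKO control 1 changed that count. Against PLKO controls 2 and 3, 15 of 405 miRNAs were higher in shLIN28B and 3 lower, and 51 and 19 passed at an unadjusted p under 0.05. The replicate block, in which samples of the same number are paired, ended all of these calls (0 higher, 0 lower, smallest adjusted p 0.409). It left shLIN28B 1 without a partner and 1 residual degree of freedom, and most fold changes moved little, from 1.23 to 1.22 for miR-16-2* and from 1.86 to 1.84 for miR-27a*, with the largest shift for miR-1274b (5.18 to 5.85). The lost calls therefore do not show that pairing accounts for the differences. The alternatives without PLKO control 1 that combine it with another setting, and the naming of these 18 miRNAs, were chosen after their values were seen. Leaving out any other single library left 0 calls.

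Among the 15 higher miRNAs, 8 were starred strands, the strand of a hairpin that is usually the less abundant. miR-16-2* stood at 18639 ± 651 CPM (SD, n = 3) in shLIN28B and 7942 ± 358 (SD, n = 2) in PLKO controls 2 and 3 (log2 fold change 1.23 ± 0.12, adjusted p = 2.31e-05). miR-27a* stood at 9346 ± 2304 against 2569 ± 717 CPM (1.86 ± 0.21, adjusted p = 9.15e-05). miR-195* (2.32), miR-141* (1.78), miR-424* (1.10), miR-200a* (1.05), miR-30e* (0.75) and miR-182* (5.40) were also higher. With median centring added only 7 of the 18 calls were kept, among them miR-27a*, miR-195* and miR-182*, while miR-16-2* (0.76, adjusted p = 0.433), miR-141*, miR-424*, miR-200a* and miR-30e* were lost. Centring lowers all log2 fold changes by the same amount, set over all 405 tested rows, low ones included. Their median log2 fold change was 0.43, against 0.07 for the 139 rows without a star at a mean of at least 100 CPM. Centring takes a different value off each library, so it also alters the spread within groups. Besides miR-27a* and miR-195*, the calls kept were those of miR-182*, miR-548o, miR-1301, miR-577 and miR-1274b, which PLKO control 3 listed at 0. The miR-30e* call held in 2 of the 8 settings without PLKO control 1. miR-141 and miR-200a belong to the miR-200 family, which marks epithelial cells. miR-16 from the mir-16-2 hairpin was higher by 1.10 ± 0.27 and miR-21 by 0.42 ± 0.11 (adjusted p = 0.0434), although with PLKO control 1 included the miR-21 log2 fold change was -0.57. The miR-21 call held in 3 of the 8 settings without PLKO control 1, and with median centring its log2 fold change there was -0.05 (adjusted p = 0.988). miR-1974 (0.87) and miR-1274b (5.18) were higher as well, and both names have been assigned to fragments of tRNA. The calls of miR-21, miR-16, miR-1974 and miR-30e* were lost with median centring, with a pseudocount of 0.1 CPM and with a mean of at least 10 CPM. In each of the last 2 settings their log2 fold changes stayed at 0.42, 1.10, 0.87 and 0.75, and only the adjusted p moved past the threshold.

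miR-548o (6.70), miR-1301 (6.40), miR-577 (5.82), miR-182* and miR-1274b had the largest fold changes, and all 5 were listed at 0 in PLKO control 3. Their size depended on the pseudocount, since miR-548o was at 5.53 with 5 CPM and 8.37 with 0.1 CPM. With 0.1 CPM, which ended 9 of the 18 calls, those of miR-548o, miR-577, miR-182* and miR-1274b were lost, and with a mean of at least 10 CPM those of miR-548o, miR-182* and miR-1274b. Against PLKO control 2 alone the shLIN28B mean was 6.54-fold higher for miR-548o, 18.3-fold for miR-1301, 14.9-fold for miR-577, 7.02-fold for miR-182* and 6.78-fold for miR-1274b, where PLKO control 2 held 258, 24.9, 16.6, 41.6 and 41.6 CPM. Lower in shLIN28B were miR-143, which is abundant in smooth muscle and fibroblasts (-0.61 ± 0.12, adjusted p = 0.00890), miR-320a (-0.55 ± 0.11, adjusted p = 0.0106) and miR-27b (-0.34 ± 0.09, adjusted p = 0.0490). All 3 lost their calls with median centring, and miR-27b, called in 2 of the 8 settings, also with 0.1 CPM and with a mean of at least 10 CPM. With centring their log2 fold changes were larger in size, at -1.08, -1.02 and -0.81, so smaller differences do not account for these lost calls. miR-27b stayed at -0.34 with 0.1 CPM and with a mean of at least 10 CPM. In PLKO control 1 miR-143 stood at 84.6 CPM against 31436 and 31644 in the other controls, and with that library included the log2 fold changes were 2.23 for miR-143, 0.89 for miR-320a and 2.17 for miR-27b. With both PLKO controls 1 and 3 left out 15 were higher and 2 lower, of which 15 were shared with the 18, but only 1 control library then remained and the spread came from shLIN28B alone, so this is no independent support.

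**Figure D2:**
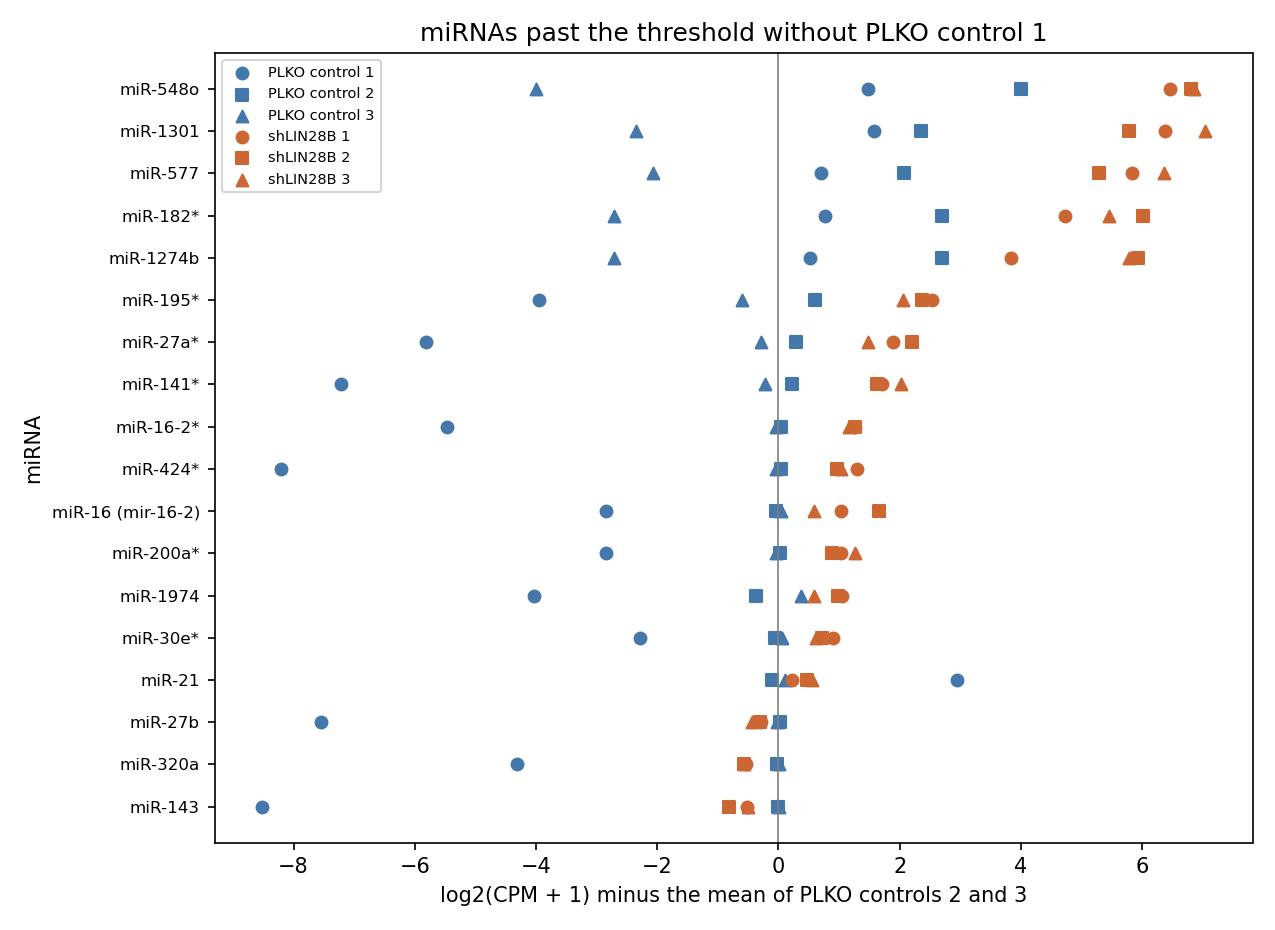
log2(CPM + 1) of each library minus the mean of PLKO controls 2 and 3 (x axis), for the 18 miRNAs (y axis) that passed the threshold without PLKO control 1, with PLKO libraries in blue, shLIN28B in orange and 1 marker per library. The 3 shLIN28B libraries lie right of the controls' mean for the 15 higher miRNAs and left of it for miR-143, miR-320a and miR-27b. PLKO control 1 lies far from the other controls for most miRNAs, and for the 5 miRNAs listed at 0 in PLKO control 3 the mean falls between PLKO controls 2 and 3.

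The let-7 family was the family the knockdown addresses. With all 6 libraries, 12 family rows were tested and 0 passed, either over all miRNAs or adjusted over the list alone. Each of the 12 log2 fold changes was above 0, with a median of 1.15, which was 0.13 above the median of all miRNAs. Rows of 1 mature name, as for let-7a and let-7f, may share reads and are not independent. The let-7 median was 0.24 without PLKO control 1, which was 0.19 below the median of all, and 0 members passed. The 139 rows without a star at a mean of at least 100 CPM had a lower median there, 0.07. Whether let-7 lay above or below other miRNAs thus depended on the rows compared, and not all let-7 rows reach that level. let-7a from the let-7a-2 hairpin had the smallest p there (0.36, 95% confidence interval 0.08 to 0.63, adjusted p = 0.163), and let-7c was at 0.83 ± 0.39 and let-7e at -0.31 ± 0.26. The sign of the family median was reversed, at -0.23, by median centring without PLKO control 1 and also in edgeR without PLKO control 3, where 0 miRNAs passed and 4 were higher and 62 lower at an unadjusted p under 0.05. Centring moved all rows alike, so the family median stayed 0.19 below the median of all. Members of this family differ by few bases and the counting rule is not given, so single family values are uncertain.

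**Figure D3:**
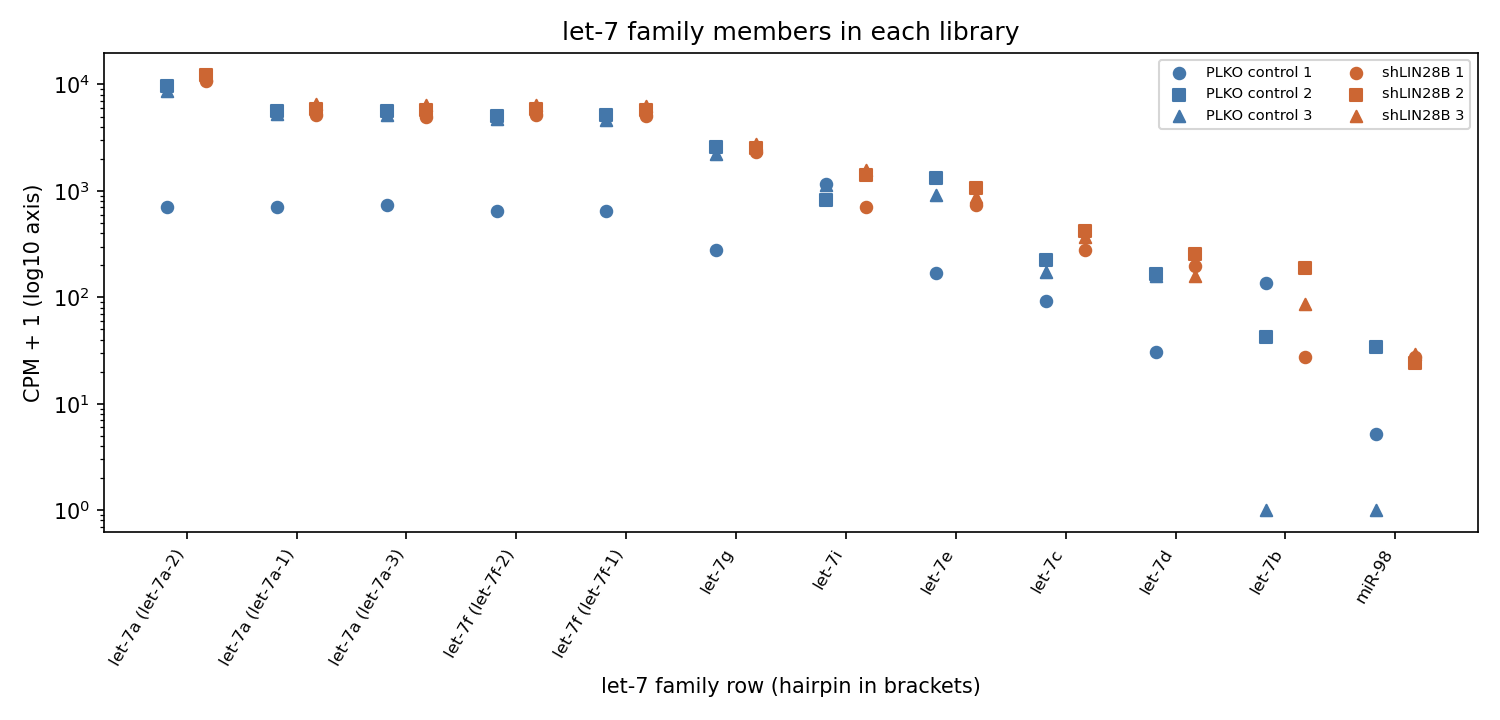
CPM + 1 (log10 axis) of the 12 let-7 family rows (x axis) in each library, PLKO controls in blue and shLIN28B in orange, with 1 marker per replicate number. PLKO control 1 lies below the other libraries in most rows, and let-7b and miR-98 are listed at 0 in PLKO control 3.

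Summed over the family, let-7 stood at 24965 ± 17103 CPM (SD, n = 3) in PLKO controls and 40161 ± 4266 (SD, n = 3) in shLIN28B, a ratio of 1.61 (2-sided exact permutation p = 0.2, where 0.1 is the smallest p that 3 against 3 allows). The sum adds every hairpin row. In PLKO control 2 the let-7f rows held 615 and 614 reads and the let-7a rows 673, 680 and 1176. Reads counted at more than 1 hairpin would enter repeatedly, so the sum may overstate the family. The shLIN28B library was higher in each of the 3 same-numbered pairs, by 30077, 5067 and 10444 CPM, and an exact sign-flip test over these pairs, added after the data were seen, gave p = 0.25, the smallest that 3 pairs allow. The single values were 5308, 36440 and 33148 in the controls and 35385, 41508 and 43592 in shLIN28B. The control mean without PLKO control 1 was 34794 ± 2328 (SD, n = 2), the ratio 1.15 and the exact permutation p 0.4, where 0.2 is the smallest possible. Median centring of all 6 libraries reversed the difference, to -211 CPM.

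Of 27 preset lists of related miRNAs, 23 had enough tested members for camera, and with all 6 libraries 0 passed. The lowest p was that of the miR-23, miR-27 and miR-24 cluster (median log2 fold change 1.83, adjusted p = 0.414). Median log2 fold changes were 1.38 for the miR-15 and miR-16 list, 0.74 for miR-17-92 and its paralogues, -0.03 for the epithelial miR-200 list, -0.14 for miR-34, 0.98 for miR-29, 0.66 for miR-30, 1.25 for miR-26, 0.41 for miR-181 and 0.72 for miR-221 and miR-222. They were 0.70 for miRNAs reported as raised in pancreatic cancer, 1.19 for the inflammatory list, 0.68 for mirtrons, 0.80 for the imprinted 14q32 cluster, 0.87 for let-7 passenger strands, 1.11 for let-7 members with a GAU motif, 0.95 for the let-7 cluster neighbours and 0.35 for the list with a GGAG loop. Leaving out PLKO control 1 reversed the sign for miR-200 (0.36), miR-34 (0.96), miR-221 and miR-222 (-0.20), the let-7 cluster neighbours (-0.14) and the GGAG list (-0.04), and lowered the miR-23, miR-27 and miR-24 median to 0.43, miR-26 to 0.33 and miR-30 to 0.08. For 12 lists a positive median went with a camera direction of down. Of these, 11 had a median below that of all miRNAs, while the median of the fibroblast and muscle list lay 0.93 above it. The list of let-7c and let-7e (2 rows), miR-210 alone and the pluripotency list (1 row) were too small to test. In fry, which tests movement in 1 direction without comparison with other miRNAs, the pancreatic cancer list had an adjusted p of 0.0394, while 0 of its 17 members passed singly. That list (0.0264) and the miR-200 list (0.0234) passed in fry without PLKO control 1 and neither passed in camera. The direction that fry gave was not kept. The median log2 fold change of all miRNAs was itself above 0, at 1.02 with all 6 libraries and 0.43 without PLKO control 1. Passing in fry therefore does not set these lists apart from that shift.

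Markers of other cell types were measured beside these lists. Summed CPM of the fibroblast and muscle list was 122 in PLKO control 1, 31553 and 31723 in the other controls and 18088 to 22350 in shLIN28B. Outside PLKO control 1 nearly all of this was miR-143, at 31436 and 31644 CPM in PLKO controls 2 and 3. miR-145 held at most 2 reads in those libraries, so the sum does not describe the list as a whole. The list's median and mean log2 fold change were above 0 while camera's direction was down. The neuronal list, which miR-9 dominates, summed to 7986 CPM in PLKO control 1 and 105294 to 136541 in the others. This sum adds the miR-9 row of each hairpin. These rows held equal or nearly equal reads in each library (5108 each in PLKO control 2), so it overstates miR-9 if they are the same reads. The blood list summed to 2049 to 5894 CPM over the 6 libraries, nearly all of it miR-486, while its miR-451 and miR-142 rows held at most 2 reads. The pancreatic acinar and islet list summed to 28.5 CPM in PLKO control 1 and at most 614 in the others, and miR-122 of liver was listed at 0 in 5 libraries. Leaving out PLKO control 1 reversed the sign of the median log2 fold change of the neuronal list (1.19 to -0.07) and of the blood list (0.23 to -0.02). The liver list was too small to test, and none of the others passed in camera.

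In camera only 1 list passed without PLKO control 1, that of miR-15 and miR-16 relatives, of which 4 of 13 members rose (miR-16-2*, miR-195*, miR-424* and miR-16 from mir-16-2) and 9 did not pass (median log2 fold change 1.10, camera adjusted p = 0.0171). The call was lost with an estimated correlation (adjusted p = 0.726 with an estimated correlation) and under the replicate block (adjusted p = 0.377), and the list did not pass in fry (adjusted p = 0.18). In the miR-200 list 2 of 9 members rose, miR-141* and miR-200a*, and 7 did not pass (camera adjusted p = 0.278). In the miR-23, miR-27 and miR-24 list miR-27a* rose and miR-27b fell, and 10 of 12 members did not pass.

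The ratio of the strands of a hairpin does not depend on how libraries are scaled, apart from the 1 CPM added to each strand, which matters for low strands. Of 70 hairpins with both strands at a mean of at least 10 CPM, 0 had a changed ratio, with 6 at an unadjusted p under 0.05 in limma. The ratio of the 5p to the 3p strand, or of the unstarred to the starred strand, had a median log2 change of -0.82, and 49 of 70 were negative, towards the 3p or starred strand in shLIN28B. Without PLKO control 1, 46 of 67 were negative, 0 passed, 3 had an unadjusted p under 0.05, and the median was -0.47. Leaving out PLKO control 2 gave 1 changed ratio. In simulated libraries none of which stood apart, 12 of 12 hairpins with an 8-fold change of a starred strand at a mean of at least 200 CPM were recovered, 4 of 12 with a 4-fold change and 0 of 12 with a 2-fold change. With starred strands at a mean of at least 10 CPM, the filter of the test, 9 of 11, 2 of 11 and 0 of 11 were recovered. In the measured libraries log2 ratio changes of -4.34 for mir-10a and -4.43 for mir-182 did not pass (adjusted p = 0.475 each), so the count of 0 does not exclude changes of 8-fold. The starred strands of these hairpins held 2 and 5 reads in PLKO control 2 and were listed at 0 in PLKO control 3. The size of their changes therefore depends on the 1 CPM added. Other ratios with a strand at 0 in that library carry the same limit.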

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

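Library weights, averaging of a mature name, edgeR, pairing of summed let-7 and every setting combined with leaving out PLKO control 1 were chosen after seeing the data; the other settings were planned. With all 6 libraries the count of miRNAs past the threshold stayed at 0 under each pseudocount, filter, scaling, trend and library-weight setting and under the replicate block (0 higher and 0 lower, 29 higher at an unadjusted p under 0.05), and the block changed no list, let-7 or strand-ratio call either. Leaving out 1 library at a time gave 0 to 15 higher and 0 to 3 lower, 0 to 1 lists and 0 to 1 strand ratios, the highest counts of miRNAs and lists being those without PLKO control 1. With rows of a mature name averaged, 0 of 366 names passed, and without PLKO control 1 10 were higher and 2 lower of 362. Depth limits all of this, since 1 read was worth 23.3 CPM in shLIN28B 2.

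The counts without PLKO control 1 also depended on the setting. A pseudocount of 5 CPM gave 23 higher and 3 lower, 0.1 CPM 7 and 2, a mean of at least 10 CPM 8 and 2, and median centring 11 and 2 (7 of these 13 among the 18). Leaving out PLKO control 3 too gave 15 and 2, and edgeR without PLKO controls 1 and 3 13 and 2 (13 of these among the 18). In both, PLKO control 2 was the only control and shLIN28B alone supplied the spread, so they are no evidence of robustness. The replicate block gave 0 and 0, with 23 higher and 12 lower at an unadjusted p under 0.05. That block left shLIN28B 1 without a partner and 1 residual degree of freedom. The miR-15 and miR-16 list was the 1 list higher with either pseudocount, and 0 lists passed under the block. With an estimated correlation it did not pass at 5 CPM (adjusted p = 0.741) or 0.1 CPM (0.696), nor in fry (0.177 and 0.175). It was also the 1 list higher without PLKO controls 1 and 3, again with 1 control library, where it did not pass with an estimated correlation (adjusted p = 0.963) or in fry (0.775).

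The let-7 median log2 fold change, 1.15 with all 6 libraries, was 0.14 with median centring, 0.11 with quantile normalization, 0.34 with library weights and 0.24 to 1.63 with 1 library left out. With PLKO control 1 left out it was 0.24 with either pseudocount and the higher filter, 0.31 with the block and -0.23 with median centring. Without PLKO controls 1 and 3 it was 0.17 in limma and 0.014 in edgeR, and edgeR without PLKO control 3 gave -0.23. The difference in summed let-7 CPM was reversed by median centring (-211). The cause of these changes was not tested, and settings that combine leaving out PLKO control 1 with another choice do not separate the effects of the choices.

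Log2 fold changes that changed sign are given by setting for let-7 members and the 5 most abundant miRNAs. Of the other list members with the smallest p, leaving out PLKO control 1 turned miR-221 from 0.72 to -0.46, miR-375 from 1.00 to -0.46, miR-125a-5p from 2.73 to -0.12, miR-486-3p from 1.57 to -1.36 and miR-486-5p from -0.23 to 0.02, besides miR-143. Median centring gave let-7e -0.42 and let-7i -0.85. Quantile normalization gave let-7b -0.0096, let-7d -0.037, let-7e -0.35, let-7i -0.81, miR-98 -0.027 and miR-21 0.41. Library weights gave let-7e -0.19, miR-21 0.44, miR-27b -0.23, miR-151-3p -0.12 and miR-9 -0.21. Leaving out PLKO control 1 alone, or with either pseudocount or the higher filter, gave let-7e at -0.31, miR-21 0.42, miR-27b -0.34, miR-203 -0.095, miR-151-3p -0.20 and miR-9 -0.26. With the block added they were -0.17, 0.51, -0.37, -0.020, -0.20 and -0.30. Without PLKO controls 1 and 3 let-7e was at -0.57, let-7g -0.038, miR-98 -0.34, miR-21 0.53, miR-27b -0.36, miR-203 -0.12, miR-151-3p -0.22 and miR-9 -0.23. Median centring without PLKO control 1 gave -0.40, -0.38 and -0.11 for let-7a from hairpins 3, 1 and 2, let-7d -0.17, let-7e -0.78, let-7f -0.25 and -0.24, let-7g -0.40, let-7i -0.22, miR-27b -0.81, miR-203 -0.57, miR-151-3p -0.67 and miR-9 -0.73. miR-21 was at -0.051 there, the sign it had with all 6 libraries but not without PLKO control 1 alone. edgeR without PLKO control 3 gave let-7a -0.24 and -0.18, let-7b -2.83, let-7c -0.66, let-7d -0.22, let-7e -0.82, let-7f -0.076 and -0.064, let-7g -0.16, let-7i -2.29 and miR-98 -0.53. edgeR without PLKO controls 1 and 3 gave let-7a -0.13 and -0.11, let-7e -0.73, let-7g -0.19, miR-98 -0.45, miR-21 0.38, miR-27b -0.52, miR-203 -0.27, miR-151-3p -0.37 and miR-9 -0.38. With 1 library left out in turn the ranges were -0.0043 to 3.55 for let-7b, -0.31 to 1.18 for let-7e, 0.069 to 1.68 for let-7g, -0.060 to 0.52 for let-7i, 1.02 to 3.57 for miR-98, -1.11 to 0.42 for miR-21, -0.34 to 3.44 for miR-27b, -0.095 to 3.71 for miR-203, -0.20 to 2.27 for miR-151-3p and -0.26 to 1.93 for miR-9.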

Other observations

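Chosen after the result was seen were the tests of a label swap, of library scaling and of a change in all starred strands, both tests of the zeros in PLKO control 3, and the counts over other splits of the libraries. The let-7a row of the let-7a-2 hairpin held more CPM than the let-7a-1 row in each library, by 4123 and 3368 CPM in PLKO controls 2 and 3 and by 5700, 6518 and 5634 in shLIN28B 1, 2 and 3, while the excess was 9.22 CPM in PLKO control 1. The rows share the mature name and differ in the hairpin that the reads were counted at. miR-720, a name since assigned to a tRNA fragment, stood at 1.68 CPM in PLKO control 1 and 33802 to 62247 CPM in the others.

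PLKO control 1 stood apart from all 5 other libraries. Thinning to 42956 reads did not decide whether depth accounts for this. After it the library's median Spearman's rho with the others was 0.489 (0.440 to 0.547 over 200 draws), over miRNAs at a mean of at least 100 CPM in those 5. The lowest rho among the others was 0.871 on average (without PLKO control 3, whose read recovery was not verified, 0.474 against 0.924). miR-21 kept most of the thinned reads of PLKO control 1, so fewer were left for its other miRNAs than in the other libraries. That can itself lower rho. The share taken by miR-21 did not account for it, since without miR-21 the SD of its log2 ratios to the mean of PLKO controls 2 and 3 was 3.17, against 1.80 between those controls. A swap with a shLIN28B library was argued against, since the lowest rho among shLIN28B libraries exceeded the highest rho of PLKO control 1 with any of them by 0.196. A wrong label with no partner, another RNA source or a different library preparation may account for it and stayed open, and no biological explanation was tested. For some mature names, reads also divided over hairpins differently in this library. Whether reads were counted alike in all libraries was not tested.

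Starred strands took more of the CPM in the 3 shLIN28B libraries than in PLKO controls 2 and 3. A factor that scales all rows of a library alike cancels in this share of CPM and cannot account for it. The test set for scaling did not decide whether the change lay within hairpins. There the lowest shLIN28B library differed from the higher control by -0.0039 in the median log2 ratio of starred to unstarred strand over 23 hairpins, with a bootstrap interval of -2.03 to 1.33. Thinning decided nothing, because that difference was absent before thinning (0.131 after it, SD 0.436 over draws). Of 31 starred rows at a mean of at least 100 CPM, 77.4% were higher (exact 95% interval 58.9% to 90.4%), against 54.7% of 139 other rows, too few to separate a change in all starred strands from a change in some. The knockdown stays among the open explanations, which may include a library preparation that differed between groups.

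PLKO control 3 listed 6 miRNAs at 0 that held at least 10 expected reads by their level in PLKO control 2, where counting noise gives 0.00020. These were miR-22*, miR-205*, miR-548o, miR-877, miR-573 and miR-548p. By the levels in shLIN28B 1, 2 and 3 the counts of such pairs in PLKO control 3 were 14, 26 and 22, to which a difference between the groups may add. Outside PLKO control 1, the only other library with such pairs was shLIN28B 3, with 2 by the level in shLIN28B 2. Depth was argued against although read recovery in this library was not verified, because 1 read cannot be worth more than its smallest value above 0, 7.87 CPM, so the expected reads are lower bounds. A minimum read count was argued against for the same reason, since no minimum can lie above that 7.87 CPM and the 6 stood at 83.1 CPM or more in PLKO control 2. What removed these miRNAs stayed open, and it may bear on the 5 largest fold changes without PLKO control 1, all at 0 in this library, although of these only miR-548o is among the 6 and the others held 2 to 5 reads in PLKO control 2.

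Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. All 10 splits gave at least the real count of 0 miRNAs (highest other 0), 0 let-7 members (highest other 0), 0 lists (highest other 2) and 0 strand ratios (highest other 3). Any split must reach a real count of 0, so these comparisons decided nothing. With PLKO control 1 left out, 10 splits of 5 libraries were also too few, and 2 gave at least the real count of 18. PLKO control 2 with shLIN28B 1 against the rest gave 38, more than the real split, and the other 8 gave 0 each. PLKO control 2 and shLIN28B 1 listed 148 and 91 pairs at 0, fewer than PLKO control 3 (264), shLIN28B 2 (186) and shLIN28B 3 (218). Whether the 38 follow from these zeros or from another structure of the samples that the groups do not describe was not tested.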
